A study of Arabidopsis thaliana with 24 samples.

How the data were processed

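The samples were strand-specific single-end RNA-seq libraries of Arabidopsis thaliana, made from WT (Col-0) and clf-28 plants. Roots and shoots came from plants aged 2 weeks, and inflorescences and siliques from plants aged 5 weeks. Each of the 8 groups, 1 per genotype and tissue, held 3 libraries, 24 in all, and groups were taken from the labels and the column names, which give genotype, tissue and replicate.

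The authors deposited a table of FPKM (fragments scaled to transcript length and library size) with 1 column per library. Per the labels they used TopHat, Cufflinks and Cuffdiff on TAIR10, with versions not given. Per the file headers each FPKM value has a status beside it. Of these, 113 values were FAIL and 15 were HIDATA, in 61 table lines, and each such value was listed at 0. The 48 deposited columns with confidence bounds were not used. The table held 34178 lines, of which 32102 named 1 gene, 1312 named several genes merged into 1 locus and 764 named none. Of 33540 gene IDs, 1357 were spread over several lines, so a call on any of those genes is uncertain. Gene names and classes came from a TAIR10.1 annotation, in which 32799 of the IDs were found, and loci were printed as the deposited table gives them. Read depth per library is unknown. FPKM sums, which are not depths, ran from 849519 to 1334840. To look for whole-read steps, the ratio of each of the 23 other libraries to WT roots replicate 1 was binned at a width of 1% over genes under 0.3 FPKM in both. The commonest bin held 0.958% to 2.04% of these genes and showed no such steps, so no read counts were recovered, no test on counts was run, and no counting interval or detection floor can be given.

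Genes at 1 FPKM or more in at least 3 libraries were kept (24439 genes). Values were taken as log2(FPKM + 1) on the deposited scaling, so every log2 fold change below includes that pseudocount of 1 FPKM, which pulls changes of weakly expressed genes towards 0. One limma model (limma 3.58.1, R 4.3.3) with a mean per group was fitted to all 24 libraries, with 16 residual degrees of freedom, an intensity trend and a robust prior. The contrasts were clf-28 minus WT in each tissue, their average over the 4 tissues, and an F test of the genotype by tissue interaction. All tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The method was tested on simulated data built from the means of the 4 tissues. Each gene had a common spread, taken within all 8 groups together and given to every library. Equal spread across tissues thus held by construction, so the shares below do not test calls made where tissues differ in spread. Changes were put into 200 genes in clf-28 roots, drawn from those above a set mean level, so recovery of weakly expressed genes was not tested. With 24 libraries the spread includes the 2 doubted libraries described below. With 24 libraries and 24120 genes the method recovered 53% of genes changed 2-fold and 80% of those changed 4-fold, with 4 unchanged genes among 137 calls. With 22 libraries and 24113 genes the shares were 66% and 93%, with 14 unchanged genes among 173 calls.

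Gene lists, 19 in number, were fixed from textbook knowledge before the data were examined. They covered Polycomb components, Polycomb opponents, floral organ identity, flowering time, meristem regulators, seed maturation regulators, seed storage and oil body, lipid biosynthesis, endosperm, seed coat, photosynthesis, pollen, tapetum and pollen wall, root cell types, auxin synthesis and transport, heat shock, touch, wound and jasmonate, defence and senescence, and reference genes. Of 259 entries 243 were matched, and the 16 others lay in merged loci. For 11 entries the gene was spread over several lines. Among lines naming only that gene, the one with the highest mean FPKM was used, so a call on another line is not counted in the lists. Each list was tested per tissue with camera at a preset correlation of 0.01, adjusted over 76 tests, with camera at an estimated correlation and fry beside it. Overlaps between tissues were set against the product of the 2 list sizes over the genes tested, with a hypergeometric p. Non-coding RNA, microRNA and pseudogene classes were compared with protein-coding genes by Fisher's exact test. The annotation gave no class of transposable element genes, so that planned test was not run.

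Genes were named by a rule fixed before the data were examined. Per tissue it took CLF, the 10 largest rises and 10 largest falls among genes that passed the test, changed at least 2-fold, reached a mean of 1 FPKM in a group, had WT and clf-28 values that did not overlap (chance gives 10% for 3 against 3) and carried a symbol, and up to 4 members of each list with the smallest p. Over tissues it took the 10 genes called the same way in most tissues. Genes outside the rule are said to be so.

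The libraries labelled clf-28 shoots replicate 3 and clf-28 siliques replicate 3 matched the other tissue, and were neither exchanged nor regrouped. The counts of genes per tissue, on average and for the interaction were repeated without those 2 (22 libraries, 24335 genes, 14 residual degrees of freedom), without those and WT siliques replicate 1 (21 libraries), and without those and the 4 WT replicate 1 libraries (18 libraries, 23911 genes, 10 residual degrees of freedom). List, several-tissue and added-list counts were repeated over 22 and 18 libraries, and overlaps and classes over 22. These sets were chosen after seeing the data, and leaving out libraries that stand apart lowers the residual spread by construction, so the higher counts they give are not independent evidence. For shoots and siliques, where 1 of 3 clf-28 libraries was in doubt, the naming rule was repeated on the 22 libraries, and the chance share of non-overlap there is 20%. Other alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization within a tissue, limma without trend and robust prior, the replicate number as a block, only genes with status OK, a fit on the libraries of the tissue alone, and each library left out in turn. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.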

Results

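Transcript levels were compared between WT plants and the clf-28 mutant of CURLY LEAF (CLF), which encodes a Polycomb-group histone methyltransferase, to find the transcripts that depend on CLF in 4 tissues. The deposited FPKM covered roots and shoots at 2 weeks and inflorescences and siliques at 5 weeks, with 3 biological replicates per genotype and tissue. Between 18532 and 20840 loci reached 1 FPKM in a library. Sequencing depth is unknown, so what could not be detected cannot be separated from what was absent.

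In 22 of the 24 libraries the profile matched the labelled tissue. The library labelled clf-28 shoots replicate 3 had a mean Spearman correlation across genes of 0.766 with the other clf-28 shoots and 0.978 with clf-28 siliques replicates 1 and 2. The library labelled clf-28 siliques replicate 3 had 0.775 with its own group and 0.986 with clf-28 shoots replicates 1 and 2. Genes are not independent replicates, so these correlations carry no test. In clf-28 shoots replicate 3 the 93 genes that marked the other clf-28 shoots stood at a median of 0.149% of their shoot level, and at 95.9% in the library labelled clf-28 siliques replicate 3. Both libraries stay in the counts as labelled, and each tissue is also given without them.

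**Figure D1:**
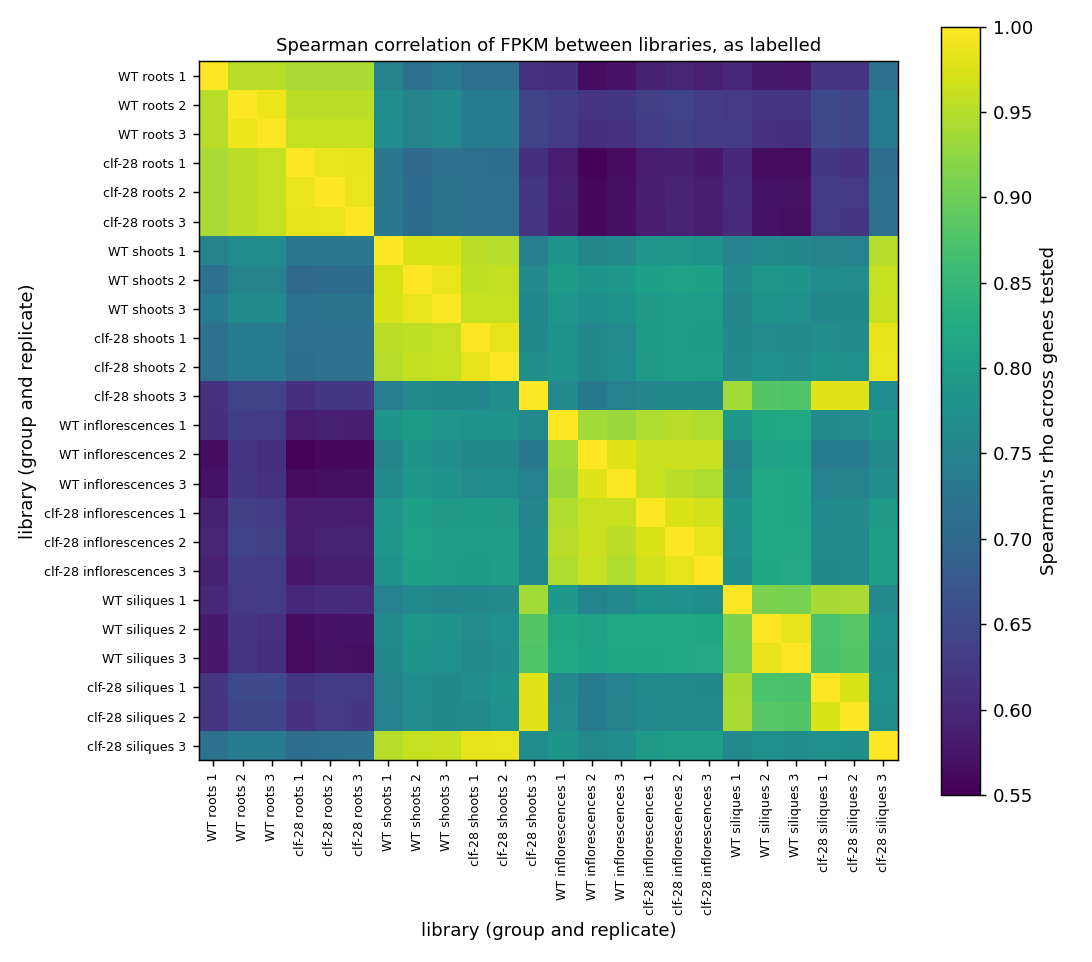
Spearman correlation of FPKM across genes between all 24 libraries, ordered as labelled, with the colour scale giving rho. The libraries labelled clf-28 shoots 3 and clf-28 siliques 3 lie off their groups, at 0.766 and 0.775 with their own and at 0.978 and 0.986 with the other.

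The CLF transcript (AT2G23380, chromosome 2, 9952867 to 9963623, TAIR10) was not called lower in clf-28 in any tissue. In roots it was 12.0 ± 3.43 FPKM in WT and 7.76 ± 0.334 in clf-28 (SD, n = 3), with a log2 fold change of -0.54 (adjusted p = 0.485). Inflorescences had 7.69 ± 0.497 in WT and 15.7 ± 3.68 in clf-28, a log2 difference of 0.93 (adjusted p = 0.19). In siliques the levels were 6.21 ± 0.207 and 12.5 ± 6.27 (0.79, adjusted p = 0.0675), and in shoots 8.03 ± 0.986 and 9.40 ± 3.57 (0.16, adjusted p = 0.799). Without the 2 libraries CLF was called higher in inflorescences (adjusted p = 0.0113) and siliques (1.16, adjusted p = 0.00081), and the shoots value turned to -0.11. The inflorescence call over 22 libraries was lost without clf-28 inflorescences replicate 3 (0.77), and without WT roots replicate 1 the roots value was -0.78 and was called lower. Gene-level FPKM does not resolve the lesion, so these values do not check the genotype of a library.

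**Figure D2:**
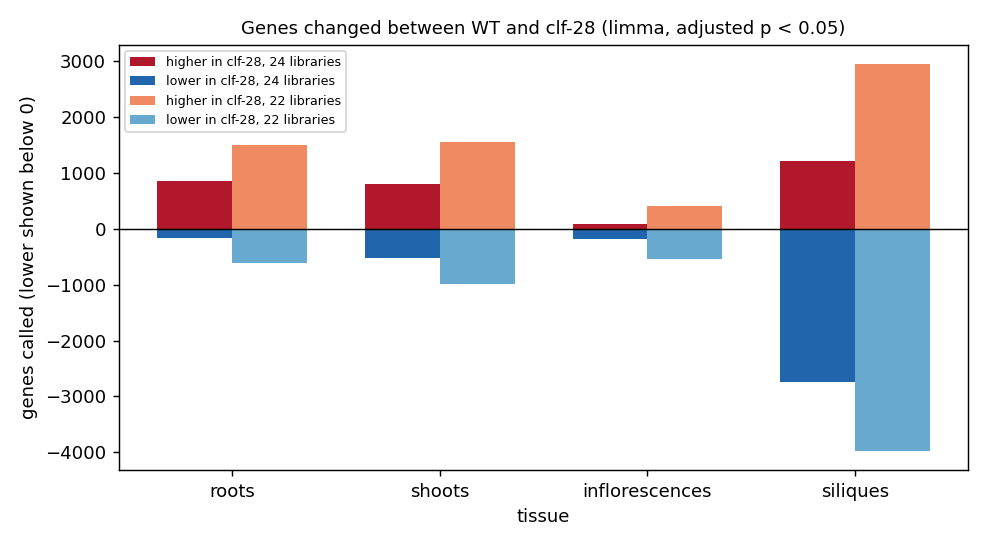
Number of genes called in each tissue at an adjusted p under 0.05, with higher in clf-28 above 0 and lower below it, for all 24 libraries as labelled and for 22 libraries. With the spread shared by all tissues, siliques had the largest counts, 3945 and 6926, and inflorescences the smallest, 283 and 955. The silique libraries alone gave 0 and 1039.

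In clf-28 roots, the jasmonate signalling genes JAZ10 and JAZ8 were among the largest rises, and a nitrate transporter gene and a thiamine synthesis gene were among the largest falls. JAZ10, a repressor of jasmonate signalling, was at 3.64 ± 1.51 FPKM in WT and 103 ± 2.99 in clf-28 (log2 fold change 4.55, SE 0.33, adjusted p = 4.09e-08, n = 3). JAZ8, of the same family, rose by 4.93, the galactinol synthase gene GolS2 by 4.32, the late embryogenesis gene LEA7 by 4.24 and the beta-glucosidase gene BGLU24 by 4.35. NRT1.5, which loads nitrate into the xylem, went from 522 ± 167 FPKM to 88.2 ± 9.77 (-2.51, adjusted p = 0.00603), and the thiamine synthesis gene THI1 from 69.1 ± 14.8 to 16.6 ± 0.185 (-1.97). The floral homeotic gene AG (AT4G18960, chromosome 4, 10382856 to 10388539) rose from 0.0516 ± 0.0478 to 2.2 ± 0.391 FPKM (1.60, adjusted p = 0.00193, but 0.51 and adjusted p = 0.417 with a pseudocount of 5 FPKM), and WOX5, which marks the quiescent centre, from 2.69 ± 0.445 to 9.85 ± 0.346 (1.56, adjusted p = 4.25e-08).

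Among the lists, touch, wound and jasmonate genes were higher as a group in roots, with 4 of 12 members called and 7 adjusted over the list alone (camera adjusted p = 5.2e-09, but adjusted p = 0.167 with an estimated correlation). LOX3, a lipoxygenase of jasmonate synthesis, rose by 3.67 and JAZ1 by 2.44. Flowering time genes were higher as a group over 24 libraries with no member called and 2 adjusted over the list alone (adjusted p = 0.0179, 0.167 with an estimated correlation), and 4 were called over 22 libraries. Another entry of the member MAF5, which the list did not use, was called higher over 24 libraries. FLC was called over 24 libraries with median-of-ratios scaling (1.72, adjusted p = 0.0374) or quantile normalization (1.67, adjusted p = 0.0463), and over 22 libraries (1.72, adjusted p = 0.0361). The call over 22 was lost without any root library other than WT replicate 1. Photosynthesis genes were lower with 0 of 14 called over 24 libraries and 8 over 22 (adjusted p = 6.47e-05, 0.762 with an estimated correlation). The chloroplast-genome FPKM of WT roots replicate 1 was 6737 and that of the other root libraries 47.0 to 164. Of 13 root cell type genes 3 were higher, the root hair genes PRP1 (1.83), RSL4 (0.57) and EXPA18 (0.56), and the list passed no directional test (adjusted p = 0.291). EXPA18 lost its call without WT roots replicate 3 (0.45), and with a pseudocount of 0.1 FPKM all 3 did (1.89, 0.61 and 0.57, adjusted p = 0.0765, 0.497 and 0.647). The Polycomb opponent list had 1 call, AT5G46910 (0.98, adjusted p = 0.0389), which was lost when any root library other than WT replicate 3 was left out (0.81 without WT replicate 1, 1.02 without WT replicate 2, and 0.99, 0.96 and 0.99 without clf-28 replicates 1 to 3). The auxin list had 1 call, YUC5 (0.67, lost with a pseudocount of 0.1 FPKM at 0.83, adjusted p = 0.311), and the seed storage list none of 18, with a median of 1.74 (adjusted p = 0.0685). Over 24 libraries no member was called in roots among Polycomb components, seed maturation regulators, lipid biosynthesis, endosperm, seed coat, pollen, tapetum, heat shock, defence or reference genes. Over 22 libraries heat shock had 2 of 3 higher and floral organ identity 3 of 15 (camera adjusted p = 0.0466 and 0.00237, with adjusted p = 0.51 and 0.356 with an estimated correlation), and seed storage passed camera with 0 called (adjusted p = 0.0303, 0.851 with an estimated correlation).

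In roots limma called 1012 of 24439 genes, 848 higher and 164 lower in clf-28, of which 592 and 44 changed at least 2-fold. Without the 2 doubted libraries 2110 were called (1507 higher), all 1012 among them in the same direction, and without the 4 WT replicate 1 libraries as well 6083, while the 6 root libraries alone gave 2667. Leaving out clf-28 roots replicate 1, 2 or 3 gave 626, 621 and 652 genes, and quantile normalization lowered the share called higher from 83.8% to 72.9% over 24 libraries and from 71.4% to 54.2% over 22.

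In clf-28 shoots, floral organ identity and flowering time genes were higher as groups. The values in this paragraph come from 22 libraries, with clf-28 n = 2, and the as-labelled value follows where it differs in call. AG rose from 0.316 ± 0.125 to 44.0 ± 5.63 FPKM (log2 fold change 5.10, SE 0.22, adjusted p = 3.11e-10), SEP3 by 2.93, SHP2 by 2.40 and SEP4 by 2.49 (as labelled 1.63, adjusted p = 0.112). FT, which encodes the flowering signal of leaves, rose from 1.69 ± 0.148 to 29.8 ± 2.52 FPKM (3.52, adjusted p = 8.02e-08). AGL20, an activator of flowering downstream of FT, rose by 1.44 (as labelled -0.41, adjusted p = 0.891), AGL17 by 2.31 and AGL42 by 1.79. FLC, a repressor of flowering that the rule named over 24 libraries but not in its repeat over 22, rose from 5.09 ± 1.97 to 31.2 ± 6.91 FPKM (2.43, adjusted p = 0.00814), a call lost without clf-28 shoots replicate 1 (2.21).

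The floral organ identity list had 9 of 15 members higher and 12 adjusted over the list alone (camera adjusted p = 2.12e-13, 0.0173 with an estimated correlation). Flowering time had 7 of 12 higher (adjusted p = 8.71e-06, 0.0173 with an estimated correlation). Over all 24 libraries these counts were 5 and 4, with adjusted p = 0.0667 and 0.167 with an estimated correlation. Root cell type genes had 5 of 13 lower (adjusted p = 5.28e-06, 0.0781 with an estimated correlation over 22 libraries and 0.0404 over 24), among them MYB36, a regulator of endodermal differentiation (-1.16). Touch, wound and jasmonate genes had 5 of 12 higher (adjusted p = 0.0112, 0.679 with an estimated correlation), with LOX3 at 2.82 and JAZ10 at 2.35. Seed storage genes were higher as a group with 1 of 18 called (adjusted p = 0.0322, 0.851 with an estimated correlation). Auxin, endosperm, seed maturation, lipid and defence lists had 1 or 2 calls each and passed no directional test over 22 libraries, while as labelled seed storage, seed maturation and endosperm lists were higher and the auxin list lower (adjusted p = 4.7e-05, 0.0453, 0.00599 and 0.034). With an estimated correlation the first 3 of these had an adjusted p = 0.779 and the auxin list an adjusted p = 0.167. Polycomb components, Polycomb opponents, meristem regulators, photosynthesis, pollen, tapetum, seed coat, heat shock and reference genes had none.

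The naming rule on 22 libraries gave LEA7 (7.32), RD20 (5.68), NAC019 (5.35), AG (5.10), HAI1 (5.04), LTI65 (4.89) and FAMT (4.63) among the 10 largest rises. RD20 went from 8.39 ± 5.12 to 423 ± 59.9 FPKM. The receptor-like kinase gene CRK30 fell by 2.29, from 10.3 ± 4.25 to 1.22 ± 0.231 FPKM (adjusted p = 1.33e-06). As labelled these 8 genes were also called, with changes of 6.76, 5.69, 4.95, 4.76, 5.13, 3.70, 3.33 and -2.64.

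In shoots limma called 1319 genes over 24 libraries, 800 higher and 519 lower, and 2542 over 22 libraries, 1552 higher and 990 lower, with 1188 genes in both sets and in the same direction. Leaving out WT shoots replicate 1, 2 or 3 from the 24 gave 689, 839 and 874 genes, leaving out clf-28 shoots replicate 1 or 2 from the 22 gave 917 and 1041, the 6 shoot libraries alone gave 81 (3733 without the doubted library), and leaving out the WT replicate 1 libraries too gave 6444. The share called higher fell from 60.7% to 44.2% with quantile normalization over 24 libraries, so the balance of higher and lower calls depends on the scaling.

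**Figure D3:**
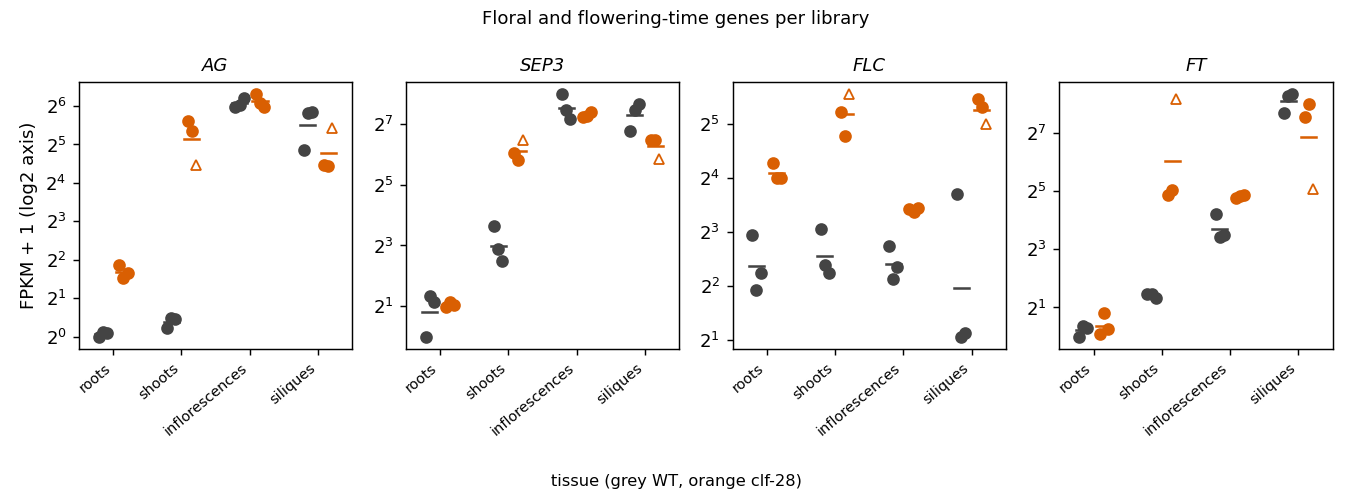
FPKM + 1 on a log2 axis of AG, SEP3, FLC and FT in each library of 4 tissues, with circles for libraries, open triangles for the 2 doubted clf-28 libraries, and bars for the mean of log2(FPKM + 1) over the 3 libraries as labelled. In shoots AG was at 0.316 in WT and 44.0 FPKM in clf-28 replicates 1 and 2.

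In clf-28 inflorescences, genes of the tapetum and pollen wall were lower, while the branching regulator TCP12 and the MADS-box gene AGL71 were higher. The tapetal gene AT5G07230 went from 139 ± 10.8 FPKM in WT to 62.3 ± 9.33 in clf-28 (log2 fold change -1.15, SE 0.14, adjusted p = 1.23e-04, n = 3), the tapetal methyltransferase gene TSM1 from 191 ± 28.8 to 68.7 ± 12.3 (-1.47), and the anther genes LTP12 and ATA20 changed by -1.38 and -1.25. SADHU5-1, a non-coding retroposon transcript, rose from 11.4 ± 3.33 to 48.2 ± 6.69 FPKM (2.02, adjusted p = 2.61e-05). AGL71 rose by 1.51, TCP12 by 1.37 and bHLH38, a transcription factor of iron deficiency, by 3.66, from 0.0382 ± 0.0347 to 14.7 ± 12.1 FPKM, a call lost with a pseudocount of 5 FPKM (1.80, adjusted p = 0.115).

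The tapetum and pollen wall list had 6 of 13 members lower and 12 adjusted over the list alone (camera adjusted p = 2.78e-23, 0.00532 with an estimated correlation). Seed storage genes were higher as a group with 0 of 18 called (adjusted p = 0.00834, 0.779 with an estimated correlation). The floral gene AP1 was lower (-1.10, adjusted p = 0.00815), as was the stem cell regulator WUS (-0.87, adjusted p = 0.0094), and the pollen gene ANX2 was higher (0.89). AP1 lost its call without clf-28 inflorescences replicate 3 (-1.0, adjusted p = 0.0661), and WUS without that library (-0.77), without clf-28 replicate 2 (-0.74) or without WT replicate 3 (-0.76). SHV2 was the 1 call of the root cell type list (-0.66). With a pseudocount of 0.1 FPKM the calls of AP1 (-1.12, adjusted p = 0.339), WUS (-0.95, adjusted p = 0.397), ANX2 (0.95, adjusted p = 0.787) and SHV2 (-1.23, adjusted p = 0.228) were lost. No member was called among the 14 other lists, flowering time included, where FLC was 4.39 ± 1.17 in WT and 9.64 ± 0.265 in clf-28 (1.00, adjusted p = 0.584). Another entry of the flowering time member MAF5, which the list did not use, was called higher, as given below. FLC was called higher by limma over 21 libraries (1.00, adjusted p = 0.0197) and over 18 (1.17, adjusted p = 6.16e-05).

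In inflorescences limma called 283 genes, 93 higher and 190 lower, and 955 over 22 libraries (416 higher, 539 lower), with all 283 among them, and 6377 without the WT replicate 1 libraries. Leaving out WT replicate 1 gave 814, clf-28 replicate 2 gave 177 and clf-28 replicate 3 gave 171, a pseudocount of 0.1 FPKM gave 67 and ended the calls of AT5G07230, TSM1, LTP12, LAP5, EXL4 and EXL6 with changes of -1.16, -1.48, -1.38, -0.75, -1.43 and -1.27, and the 6 libraries alone gave 48. WT inflorescences replicate 1 had a chloroplast-genome FPKM of 13276, against 316 to 1870 in the others.

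In clf-28 siliques, seed storage and seed maturation genes stood far above WT replicates 2 and 3, and endosperm genes stood below WT. WT siliques replicate 1 had SESA4, a seed storage albumin gene, at 5369 FPKM, while WT replicates 2 and 3 had 0.0534 and 0.51, and clf-28 replicates 1 and 2 had 36870 and 42126. Over 22 libraries SESA4 rose by 10.91 (SE 2.27, adjusted p = 0.00173), and over 24 by 8.25 (adjusted p = 0.0398). The spread of each gene was estimated over all tissues together. The SE and p given for siliques therefore do not measure the spread among the silique libraries, which was wide in WT for SESA4, FUS3, ABI3 and FLC. The maturation regulators FUS3 and ABI3 rose over 22 libraries from 9.79 ± 10.1 to 95.4 ± 39.5 FPKM (3.49) and from 5.58 ± 7.55 to 49.5 ± 0.208 (3.58), while as labelled they did not pass (adjusted p = 0.469 and 0.395). The endosperm MADS-box gene AGL38 fell from 6.59 ± 0.937 to 2.2 ± 0.0886 FPKM (-1.24, adjusted p = 5.05e-06), and the endosperm gene FWA from 18.6 ± 4.81 to 5.67 ± 0.195 (-1.53). FLC rose from 4.76 ± 6.27 to 40.9 ± 3.03 FPKM (3.42, adjusted p = 2.12e-04), with 12.0 FPKM in WT replicate 1 and 1.10 and 1.19 in the others.

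Over 22 libraries 16 of 18 seed storage genes were higher (camera adjusted p = 7.22e-08, 0.565 with an estimated correlation), 8 of 10 maturation regulators (adjusted p = 1.33e-06, 0.356 with an estimated correlation) and 16 of 21 lipid synthesis genes with 1 lower (adjusted p = 3.12e-07, 0.379 with an estimated correlation). As labelled these counts were 3, 1 and 3. Endosperm genes had 10 of 12 lower in both sets (adjusted p = 2.24e-06, 0.103 with an estimated correlation over 22), with 1 higher over 22. Of 9 seed coat genes 5 were lower, such as TT2 (-1.39) and TT12 (-1.53), and 2 were higher, among them TT10 (2.85), which acts late in the coat, and the list passed no directional test over 22 libraries (adjusted p = 0.221), while as labelled it was lower with 4 called (adjusted p = 0.0408, 0.779 with an estimated correlation). Defence genes had 5 of 8 higher and 1 lower (adjusted p = 0.00597, 0.381 with an estimated correlation), with PR1 at 4.40 and BGL2 at 2.83. Floral organ identity had 5 of 15 lower, AP3 (-1.08, a call lost with a pseudocount of 0.1 FPKM at -1.09, adjusted p = 0.184) and AG (-1.06) among them (adjusted p = 0.0466, 0.588 with an estimated correlation), a group call lost under both other scalings (adjusted p = 0.0524 and 0.0895). Heat shock (2 of 3 higher, adjusted p = 0.0196) and photosynthesis (5 of 14 lower, adjusted p = 0.00885) also passed camera, with adjusted p = 0.379 and 0.686 with an estimated correlation. The lists of meristem regulators (3 higher, 1 lower), auxin (3 and 3), Polycomb components (2 and 2), pollen (4 lower), flowering time (1 higher, 2 lower), tapetum (2 higher), root cell types (1 and 1), reference genes (1 lower) and touch, wound and jasmonate (1 lower) passed no directional test over 22 libraries, and Polycomb opponents had no call. As labelled, flowering time and touch, wound and jasmonate genes were higher with 1 called each (adjusted p = 0.034 each, 0.206 and 0.779 with an estimated correlation).

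Siliques had 3945 genes called over 24 libraries, 1208 higher and 2737 lower, and 6926 over 22, 2951 higher and 3975 lower, with 3481 in both sets and in the same direction. Without WT siliques replicate 1 as well the count was 8504, without all WT replicate 1 libraries 11799. Leaving out WT replicate 2 or 3 from the 24 gave 2040 and 1865 genes, leaving out clf-28 siliques replicate 1 from the 22 gave 3918, and the share called higher over 24 moved from 30.6% to 40.7% with median-of-ratios scaling. The 6 silique libraries alone gave 0 genes by limma (4344 at an unadjusted p under 0.05), and 1039 without the doubted library.

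**Figure D4:**
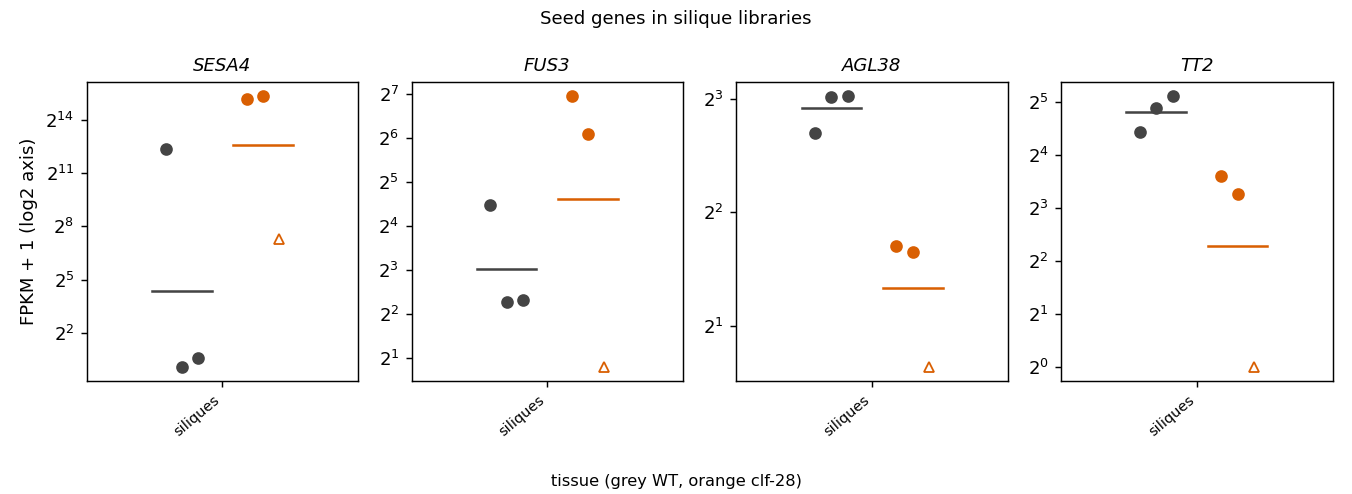
FPKM + 1 on a log2 axis of SESA4, FUS3, AGL38 and TT2 in the silique libraries, with circles for libraries in replicate order, an open triangle for the doubted clf-28 library and bars for the mean of log2(FPKM + 1) over the 3 libraries as labelled. For SESA4 the left WT circle, replicate 1, is at 5369 FPKM and the 2 others are under 1.

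Across tissues, the average change over the 4 tissues was called for 3218 genes (1545 higher, 1673 lower) and the change differed between tissues for 2566, while over 22 libraries the counts were 7047 and 6397 and over 18 libraries 12962 and 13518. The interaction count was 1663 without WT siliques replicate 2 and 1659 without replicate 3. SADHU5-1 and an entry of the flowering repressor gene MAF5, an ID spread over several entries, were called higher in all 4 tissues. SADHU5-1 rose by 2.02 in roots, 2.16 in shoots, 2.02 in inflorescences and 1.49 in siliques, and MAF5 by 0.97, 2.15, 1.67 and 0.87. Both kept these calls with each library left out in turn. The heat shock factor gene HSFA1E was also called higher in all 4 (0.58, 1.16, 0.68 and 0.64), but lost its call in roots without any library other than WT replicate 1 (0.52 and 0.55 without WT replicates 2 and 3, and 0.58 without each clf-28 library). It lost it in inflorescences without any library other than clf-28 replicate 1 (0.63, 0.71 and 0.71 without WT replicates 1 to 3, 0.57 and 0.67 without clf-28 replicates 2 and 3), and in siliques without WT replicate 2 (0.52). In all, 381 genes were higher in at least 2 tissues and 211 lower, and 5 and 0 in all 4, where 22 libraries give 22 and 12.

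Roots and shoots shared 176 higher genes where independent lists of that size give 27.8 (hypergeometric adjusted p = 7.69e-91, with genes not independent replicates), and 30 lower genes against 3.5. Shoots and siliques shared 203 higher genes against 39.5, a pair that includes both doubted libraries, and 390 against 188 over 22 libraries. Inflorescences and siliques shared 22 lower genes against 21.3 over 24 libraries (adjusted p = 0.468) and 144 against 88 over 22 (adjusted p = 7.36e-10). The tissues share the estimate of each gene's spread, so genes of low spread tend to be called in several of them. This raises overlaps by itself, which the hypergeometric p does not allow for. Called in opposite directions were 12, 92 and 21 genes for these pairs, in the order above, over 24 libraries, and 51, 214 and 180 over 22. Beside the 180, the pair of inflorescences and siliques shared the 144 lower genes and 92 higher genes over 22 libraries, the latter against 50.4. The opposite calls were not set against independent lists, so these counts do not settle whether that pair shares a response. Correlations of the log2 fold change across genes between tissues ran from 0 to 0.29 over 24 libraries and from 0.12 to 0.34 over 22.

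By class, none of 24 Fisher's exact tests of non-coding RNA, microRNA and pseudogene classes passed after adjustment over 24 libraries, and 1 had an unadjusted p under the threshold. Over 22 libraries 17 of 332 pseudogenes (5.12%) were higher in inflorescences against 1.65% of protein-coding genes (odds ratio 3.22, adjusted p = 0.00144), and 10.5% were lower in siliques against 16.8% (odds ratio 0.585, adjusted p = 0.0215).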

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

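All tests in this part other than the splits of the samples were chosen after the results were seen. Among members of the gene lists, 3 genes stood out because their change had opposite signs in 2 tissues, by a test of the difference itself over 24 libraries. Genes outside the lists were not searched in this way. Over all genes tested, 172 were called higher in a tissue and lower in another. SEP3 differed by 4.14 between shoots (3.11) and siliques (-1.03, adjusted p = 1.18e-04), but both comparisons hold a doubted library, and the silique value over 22 libraries was -0.82 and not called. ANX2 differed by 1.94 between inflorescences (0.89) and siliques (-1.05, adjusted p = 2.77e-04), where the silique comparison holds a doubted library (-0.83 and a difference of 1.72 over 22 libraries), and its inflorescence call was lost with a pseudocount of 0.1 FPKM (0.95, adjusted p = 0.787). YUC5 differed by 1.27 between roots (0.67) and shoots (-0.60, adjusted p = 3.79e-04), where the shoots comparison holds a doubted library. Its shoots call was lost with a pseudocount of 5 FPKM (-0.16) and its roots call with one of 0.1 FPKM (0.83). Over 22 libraries the YUC5 difference was 1.16, with shoots at -0.49. That shoots call was lost with the replicate number as a block (-0.51) and without WT shoots replicate 2 (-0.47). It was also lost without clf-28 shoots replicate 1 (-0.45) or 2 (-0.54).

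The libraries labelled clf-28 shoots replicate 3 and clf-28 siliques replicate 3 each match the other's tissue. A mixed sample is argued against, since markers of the labelled tissue stood at no more than 0.149% of their level in the other libraries of the group. A mislabelled sample has the values it needs, with a gain in mean Spearman correlation of at least 0.211 for the other tissue, and an exchange of the 2 may be the explanation. Whether plants, tubes or columns were exchanged stays open, and the clf-28 lesion could not be checked in these libraries. The library labelled clf-28 shoots replicate 3 correlated at 0.978 with clf-28 siliques and at 0.899 with WT siliques. That labelled clf-28 siliques replicate 3 correlated at 0.986 with clf-28 shoots and at 0.957 with WT shoots. Both profiles were thus closer to clf-28 than to WT of the other tissue.

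Transcripts that are abundant in clf-28 siliques were seen at low levels in the other clf-28 tissues. The genes were chosen at a mean of 500 FPKM or more in clf-28 siliques replicates 1 and 2. They also had to be under 1 FPKM in WT replicates 2 and 3 of the tissue, which fixes low values in those libraries. Their median percent of the silique level per library was 0.0245% to 0.198% in clf-28 and 0% to 0.0126% in WT. WT replicate 1, which the choice did not use, had 0% in roots, 0.00274% in shoots and 0.0126% in inflorescences. Reads from silique libraries would give 1 common percent, and 79.6% of values lay within 3-fold of their library's median, just under the 80% set for that explanation. The clf-28 genotype stays open as well, with 1 regulator of seed maturation called higher (ABI5 in shoots). The 2 explanations cannot be told apart, because every affected library is clf-28, so the small rises of seed storage genes outside siliques may come from either.

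Seed genes differ between clf-28 siliques and WT siliques, and also among the WT siliques. Older siliques at harvest have the values they need. The change of clf-28 replicates 1 and 2 from WT replicate 2 correlated across genes at 0.70 with the difference of WT replicate 1 from WT replicate 3, and at 0.71 with WT replicates 2 and 3 exchanged. WT replicates 2 and 3 were close to each other (Spearman 0.985) and further from replicate 1 (0.912 and 0.909). Anything that replicates 2 and 3 share enters both sides, so the exchange is no second check. The correlation cannot tell seed age from another difference of those 2 libraries. The clf-28 genotype cannot be told apart from a still later stage, since the median seed storage gene stood 1.48 log2 units above WT replicate 1 in clf-28. A difference in seed age at harvest may therefore account for part of the silique counts, and the labels give no stage.

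Other splits of the libraries were counted for each number of genes. In roots, shoots and siliques 1 of 10 splits of the 6 libraries, the real one, gave as many genes (1012, 1319 and 3945, against at most 4, 1 and 2886 in the others), and in inflorescences 2 of 10 did (283, against 595). With 10 splits the share cannot fall under 0.05. The split with 595 genes, which put WT replicate 1 with clf-28 replicates 2 and 3, points to a structure of the samples other than genotype, as does that with 2886, which put WT replicate 1 with clf-28 replicates 1 and 2. For the average over tissues and the interaction 1 of 100 splits, the real one, gave as many genes (3218 against at most 1039, and 2566 against at most 1906). That is the lowest share 100 splits can give. It argues against chance for a difference between the labelled groups in at least 1 tissue. The splits remove every such difference, so they do not test whether the change is equal across tissues. Over 22 libraries the counts were 7047 against 2307 and 6397 against 5577, also 1 of 100 each, but that set was made by leaving out libraries that stood apart from their labelled groups, so these say nothing about chance.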

How the results depend on the processing

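The sets of 22, 21 and 18 libraries were chosen after seeing the data. CLF in shoots, which was not called, changed sign, as given below. None of the other genes named from a set of libraries did so under the settings run on that set. For genes named from 22 libraries, those settings did not include the fit on all 24. There AGL20 in shoots had the other sign, though it was not called, as given above. Of the values for 75 pairs of a gene and a tissue over 24 libraries, 1218 stayed as they were, called or not. Of the others 114 lost the call and 9 gained it. For 99 pairs over 22 libraries 1395 stayed, 66 lost the call and 3 gained it. At least 1 setting ended the call of 37 of the 75 pairs and of 24 of the 99. Counts depend most on which libraries are used and on whether the tissues share the spread. The former is partly by construction, since leaving out libraries that stand apart lowers the spread. Over 24 libraries, fits on a tissue alone moved roots from 1012 to 2667 genes, shoots from 1319 to 81, inflorescences from 283 to 48 and siliques from 3945 to 0. The order of the tissues by count therefore holds only for the shared spread. Fits on a tissue alone also have fewer residual degrees of freedom, and the 2 differences were not separated. The cause was not tested for the other changes. Where 1 clf-28 library was left, it is assumed to vary like the other groups. Depth is unknown, and a test on whole reads was not run because no counts were recovered.

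Gene counts for roots, shoots, inflorescences, siliques, the average and the interaction were 1012, 1319, 283, 3945, 3218 and 2566. Without the 2 doubted libraries they were 2110, 2542, 955, 6926, 7047 and 6397, without WT siliques replicate 1 as well 3163, 3575, 1547, 8504, 9067 and 8719, and without the 4 WT replicate 1 libraries 6083, 6444, 6377, 11799, 12962 and 13518. The libraries of the tissue alone gave 2667, 81, 48 and 0, and over 22 libraries 2671 in roots, 3733 in shoots, 49 in inflorescences and 1039 in siliques. In inflorescences a pseudocount of 0.1 gave 67 (449 over 22), of 5 gave 514, no filter gave 464 and a filter of 5 FPKM gave 154. The interaction had 1675 with a pseudocount of 0.1.

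With the replicate number as a block, although correlations of same-numbered libraries of -0.218 to 0.309 show no pairing, the counts were 810 in shoots, 153 in inflorescences, 2614 in siliques, 2114 for the average and 1144 for the interaction. Over 22 libraries the block gave 1375, 1104, 362, 3961, 4011 and 2904 in the order above, and ended the CLF call in inflorescences (0.925).

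Leaving out 1 library in turn gave 621 to 1181 genes in roots, 689 to 1238 in shoots, 171 to 814 in inflorescences, 1865 to 4526 in siliques, 2394 to 4677 for the average and 1659 to 3320 for the interaction. The lowest came without clf-28 roots replicate 2, WT shoots replicate 1, clf-28 inflorescences replicate 3, and WT siliques replicate 3 (siliques and interaction), and 814 without WT inflorescences replicate 1. From the 22 libraries the ranges were 1323 to 2552, 917 to 1961, 476 to 2677, 3918 to 8504, 5228 to 9067 and 4429 to 8719, with 2677 without WT inflorescences replicate 1 (632 without WT replicate 3).

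CLF in shoots (0.157) turned to -0.108 over 22 and 21 libraries and to -0.043 over 18, with -0.108 to 0.338 on leaving out 1 library, the lowest without clf-28 shoots replicate 3. In roots (-0.538) it was called lower at -0.779 over 18 libraries, with -0.779 to -0.408 on leaving out 1 library. In inflorescences it was called higher at 0.925 over 22 and 21 libraries and at 0.91 over 18, with 0.768 to 1.09 on leaving out 1. In siliques it was called higher at 0.876 with quantile normalization, 1.158 over 22 libraries and 1.152 over 21 and 18, with 0.452 to 1.158 on leaving out 1, and 0.842 to 1.473 from the 22.

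Lists past camera numbered 3 in roots, 7 in shoots, 2 in inflorescences and 8 in siliques. With an estimated correlation they numbered 0, 1, 1 and 0, and over 22 libraries 0, 2, 1 and 0. With fry they numbered 4 in shoots, 1 in inflorescences and 4 in siliques, and over 22 libraries 6 in roots and 4 in shoots, while camera over 22 libraries gave 6 in roots. Genes changed in several tissues numbered 592, with 254 at 2-fold, 1676 over 22 libraries and 7406 over 18. Gene classes past the threshold numbered 0, and 2 over 22 libraries.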

Other observations

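The 3 gene lists in this part were chosen after the data were seen, so their counts are not independent evidence of a direction. Of 17 iron deficiency genes, 5 were higher in inflorescences and 9 in siliques over 24 libraries, while 2 were lower in roots and 1 was higher in shoots. Over 22 libraries 10 were higher and 1 lower in inflorescences, 9 were higher in siliques and 6 were lower in roots. In siliques bHLH38, a transcription factor of the iron deficiency response, went from 0.109 FPKM in WT to 6.66 in clf-28 replicates 1 and 2 (log2 fold change 2.79, adjusted p = 2.57e-05).

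Of 15 abscisic acid and dehydration genes, 7 were higher in roots, 9 in shoots, 7 in siliques and 0 in inflorescences over 24 libraries by limma, and over 22 libraries 9, 15, 7 (with 1 lower) and 0. The inflorescence count depends on the libraries used, with 10 higher and 1 lower over 18 libraries, where siliques had 8 higher and 3 lower. Of 3 axillary bud homeobox genes, 2 were higher in shoots and 1 in inflorescences, and 3 and 2 over 22 libraries. Over 22 libraries AG changed in opposite directions in shoots (5.10) and siliques (-1.06), a difference of 6.15 (adjusted p = 1.18e-08).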
